A study of Mus musculus with 23 samples.

How the data were processed

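RNA from the left ventricle of FVB mice was sequenced in 23 libraries that fall into 6 groups. Per the labels, the mice breathed filtered air, aerosol of the e-cigarette vehicle, or aerosol of the vehicle with nicotine for 4 hours a day on 5 days a week over 3 months, starting at an age of 3 weeks or 3 months. Each age had 4 air and 4 nicotine libraries, with 3 vehicle libraries at 3 weeks and 4 at 3 months. Libraries keep the replicate numbers of the labels, so that some numbers are missing. The labels do not say that the libraries are from separate animals, so the p-values measure only the spread between these samples, which may be technical. No batch, sex, cage or day is given.

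The authors deposited whole-number counts per gene, not normalized, for 49315 genes. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2 were used. The genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are given, and values of genes that overlap others or have close copies are uncertain. Columns of counts in the deposited table were matched to libraries by name, with 0 columns of no sample. The authors' deposited tables of nicotine against air at each age hold log2 fold changes and p-values, with a signal column per library that is the deposited count divided by a size factor. These signal columns were used only to check which library a column holds. A deposited table of gene ontology terms, with p-values, gene counts and a percent per term per the file headers, was not used here because it names no comparison. Gene symbols, gene types and exonic lengths came from GENCODE vM21 by gene ID, and 48970 genes had a symbol.

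Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at a minimum count of 10, which left 15500. Library sizes were scaled by TMM, and a single robust quasi-likelihood fit of the 6 groups over all 23 libraries left 17 residual degrees of freedom. For each contrast, p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and all adjusted p-values of single genes are from this test unless another tool or fit is named. The contrasts were nicotine against air, vehicle against air and nicotine against vehicle at each age, the difference of the nicotine and of the vehicle effects between ages (3 weeks minus 3 months), and 3-month against 3-week air. Levels are CPM with TMM scaling, given as mean ± SD, and log2 fold changes are given ± SE. This design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined.

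Named genes were, in each contrast, the 10 higher and 10 lower genes with the smallest p among those past the threshold with a mean log2 CPM of at least 1, and up to 4 genes past the threshold from each list. Where none passed, the 3 higher and 3 lower genes with the smallest p were named. Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1, Atp2a2, Col1a1, Cyp1a1 and Postn were followed in every contrast. Predicted gene models were counted but not named, and results of some genes were left out. The same rule was applied to the 3-month contrasts fitted on the compared groups alone. Any gene named outside it, such as those behind small counts, was chosen after its values were seen.

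In all, 37 gene lists were fixed. They cover cardiac stress and hypertrophy markers, the ventricular sarcomere, calcium handling, ion channels and connexins, extracellular matrix and fibrosis, inflammatory cytokines and NF-kB targets, the interferon response, NRF2 and antioxidant genes, aryl hydrocarbon, xenobiotic and aldehyde metabolism, fatty acid oxidation and PPAR-alpha targets, glucose uptake and glycolysis, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, integrated stress and unfolded protein responses, heat shock, the circadian clock, immediate early genes, the cell cycle, cholinergic and adrenergic receptors, glucocorticoid targets, hypoxia targets, p53 targets and cholesterol synthesis. Marker lists were added for other cells a ventricle sample could hold, namely atrial cardiomyocytes, adipocytes, blood, endothelium, fibroblasts, macrophages, T and NK cells, B and plasma cells, neutrophils, smooth muscle and pericytes, skeletal muscle, lung epithelium, mesothelium, and neurons with Schwann cells. Lists were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with enough measured members. Camera with an estimated correlation and fry were the alternatives. With the estimated correlation, 0 lists passed the threshold in any contrast. Of T and NK cell markers 2, and of lung epithelium markers 1, were measured, so these lists were not tested. Camera placed 10 lists past its threshold in no contrast, with smallest adjusted p-values of 0.0723 for neurons and Schwann cells, 0.134 for the sarcomere, 0.143 for fibroblasts, 0.193 for cholinergic and adrenergic receptors, 0.198 for B and plasma cells, 0.3 for the circadian clock and for skeletal muscle, 0.336 for smooth muscle and pericytes and for mesothelium, and 0.389 for p53 targets.

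The alternatives were size factors by RLE, no count filter, a minimum count of 50, fits of the compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, and leaving out each library of the groups compared in turn. Added after seeing the data were fits without 3-week air libraries 1 and 5 or without 3-week vehicle libraries 1 and 2, fits of a single age, and a length offset, which removes each library's trend of expression with exonic length. Camera was not run with that offset in any contrast. A covariate of sex was not run because sex-linked genes showed libraries of a single kind.

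Library totals ran from 12297955 to 17821550 counts, with 20466 to 21834 genes detected. No pair of replicates agreed within counting noise, since chi-square per degree of freedom was 4.67 to 113. The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold in each of the 6 treatment comparisons. Genes were drawn independently at the spread of all 23 libraries, with no subgroups among the libraries. The real younger libraries varied more than that, so the shares below may be too favourable for the 3-week comparisons. For 3-week nicotine against air, over 15269 genes, 65% of the 2-fold and 87% of the 4-fold changes were recovered, and 3.80% of the calls were false. For 3-month vehicle against air, over 15224 genes, these shares were 74%, 93% and 2.34%. The other comparisons, over 15248 to 15277 genes, recovered 63% to 69% and 92%, and their false shares lay above 5%, at 5.49% for 3-week nicotine against vehicle, 5.99% for 3-month nicotine against air, 6.06% for 3-week vehicle against air and 8.52% for 3-month nicotine against vehicle.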

Results

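The left ventricle, the main pumping chamber of the heart, was profiled by RNA sequencing in mice that had inhaled e-cigarette aerosol with or without nicotine, or filtered air, from either of 2 starting ages. The question was how the aerosol changes ventricular transcripts, and whether mice exposed from 3 weeks of age differ from those exposed from 3 months. Exposure lasted 3 months from either start, so starting age cannot be told apart from age at the end of exposure. No batch is given, so one between the 2 starting ages cannot be told apart either. There were 11 libraries of the younger start (4 air, 3 vehicle, 4 nicotine) and 12 of the older start, 4 per group. Library totals were 12297955 to 14713765 counts in 3-week nicotine, the shallowest group, and 14596003 to 17821550 in 3-month air.

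The younger libraries varied more than the older ones. The common biological coefficient of variation was 0.234 over the 11 younger and 0.105 over the 12 older libraries, and 0.179 when all were fitted together. In 3-week air, libraries 1 and 5 held more transcript of inflammatory genes than libraries 2 and 4 (mean log2 CPM 3.7 and 3.52 against 1.85 and 1.57), while immediate early genes were at 6.45, 5.68, 3.69 and 6.73 in libraries 1, 2, 4 and 5. Thbs1, which encodes the secreted matrix glycoprotein thrombospondin, read 742 and 690 CPM in libraries 1 and 5 against 11.9 and 6.94 CPM in libraries 2 and 4. Noncoding genes took 1.11 to 1.49% of counts in 3-week air but 2.54% and 2.15% in 3-week vehicle libraries 1 and 2, and 3.1% in 3-week nicotine library 3. The rank correlation of expression with exonic length, across genes of a library, ran from -0.348 to 0.312, and among the older mice all 4 vehicle libraries lay below 0 (-0.25 to -0.118) while air lay at 0.0817 to 0.295. Atrial cardiomyocyte markers also varied between libraries, from a mean log2 CPM of -0.0065 in 3-month nicotine library 4 to 5.34 in 3-week vehicle library 2.

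**Figure D1:**
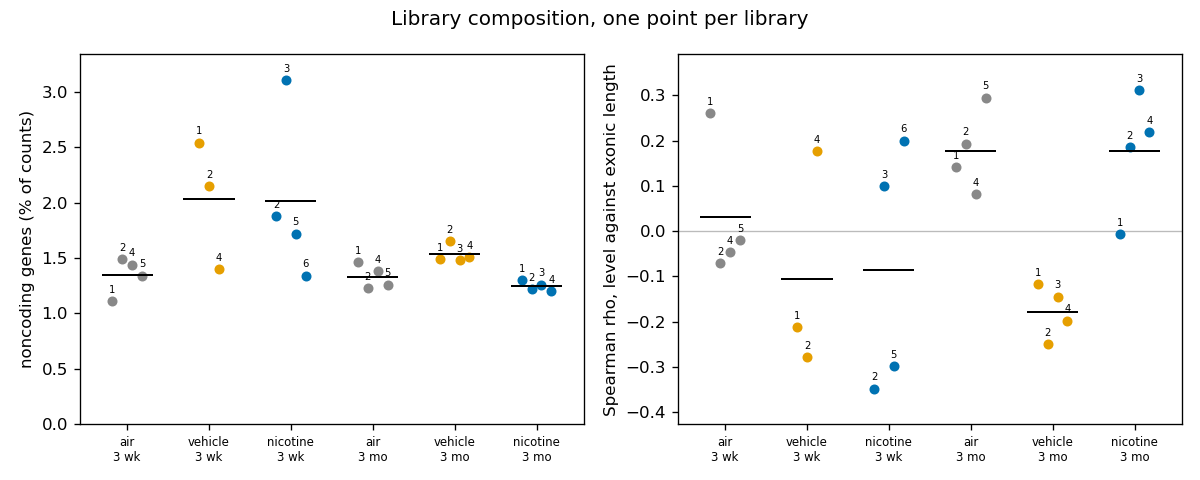
Share of counts from noncoding genes (percent, left) and Spearman correlation of expression with exonic length across genes (right) for each of the 23 libraries. Each point is a library with its replicate number, and bars are group means. The 4 older vehicle libraries lie below 0 on the right, and the younger groups spread most.

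Mice given nicotine aerosol from 3 weeks of age had less transcript of the basement membrane collagens and of the receptor Cd93 than air controls. Col4a1 and Col4a2, the main collagen chains of basement membranes, were at 359 ± 51.2 and 281 ± 42.6 CPM (n = 4) against 656 ± 43 and 491 ± 43.3 CPM (n = 4), changes of -0.87 ± 0.14 and -0.81 ± 0.13 log2 (edgeR adjusted p = 0.0121 for both). Cd93, an endothelial surface receptor, was at 93.3 ± 7.92 against 171 ± 27.4 CPM (-0.88 ± 0.12 log2, adjusted p = 0.0052), with all 4 nicotine libraries (86.8 to 104 CPM) under all 4 air libraries (147 to 203 CPM). Rit1, a small GTPase, was the higher gene with the smallest p, at 92.8 ± 5.04 against 60.9 ± 6.49 CPM (0.61 ± 0.10 log2, adjusted p = 0.0121). Of 15500 genes, 126 passed the threshold, 14 higher and 112 lower.

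Of 27 measured extracellular matrix genes, 5 fell (Col4a1, Col4a2, Thbs1, Loxl2 and Col15a1, the last by 0.72 log2, adjusted p = 0.0191) and 13 fell adjusted over the list alone. The list stood lower as a group (camera adjusted p = 1.65e-13, median -0.36 log2, and fry adjusted p = 0.00637), with an adjusted p = 0.0851 with an estimated correlation. Of 21 inflammatory and NF-kB targets, 6 fell and 17 fell adjusted over the list alone, including Tnfaip3 (-1.25 log2), Sele (-2.98), Nfkb2 (-0.50) and Cxcl2 (-4.40). Of 19 immediate early genes 15 fell adjusted over the list alone and 4 over all genes, namely Nr4a1, Egr3, Fosb and Nr4a3, a nuclear receptor at 2.79 ± 0.44 against 126 ± 142 CPM (adjusted p = 0.0121). Camera gave adjusted p = 1.16e-11 and 9.53e-09 for these lists, and adjusted p = 0.344 and 0.398 with an estimated correlation. In the immediate early list as a whole, air library 2 (mean log2 CPM 5.68) lay nearer to air libraries 1 and 5 (6.45 and 6.73) than to air library 4 (3.69). Nr4a3 set air libraries 1 and 5 apart, at 304 and 178 CPM in them and 19.3 and 4.44 CPM in the others. The stress regulators Atf3, Cdkn1a and Errfi1 fell in the same pattern, by 3.71, 3.44 and 2.66 on the log2 scale.

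Blood and erythroid markers were higher as a group in 3-week nicotine (6 measured, 5 adjusted over the list alone, median 0.84 log2, camera adjusted p = 8.32e-05), as were mitochondrially encoded genes (13 measured, 1 called, mt-Nd6, with adjusted p = 0.0745 under the length offset, 2 adjusted over the list alone, camera adjusted p = 0.000803). Genes of xenobiotic metabolism (17 measured, 0 called, 4 adjusted over the list alone, Aldh1a1, Adh1, Fmo1 and Fmo2) and nuclear genes of oxidative phosphorylation (30 measured, 0 called) were higher at camera adjusted p = 0.0203 and 0.0122. These 4 lists had adjusted p = 0.391 to 0.635 with an estimated correlation. Lower at camera adjusted p = 0.0439 or less were 9 further lists. Cardiac stress markers had 1 of 13 called (Rcan1) and 6 adjusted over the list alone (camera adjusted p = 0.00451), glucocorticoid targets 2 of 18 (Cdkn1a and Errfi1) and 6 lower with 1 higher (0.0345), and integrated stress genes 1 of 25 (Atf3) and 3 (0.0439). Neutrophil markers had 0 of 6 called and 3 adjusted over the list alone (0.022). Glycolysis (0 of 21, 0.0439), heat shock (0 of 14, 0.0115), cell cycle (0 of 23, 0.0165), adipocyte (0 of 8, 0.0103) and macrophage genes (0 of 13, 0.0115) had none by either count. With an estimated correlation these 9 lists had adjusted p = 0.454 to 0.635. Nppb, which encodes brain natriuretic peptide, was at 187 ± 26.6 against 352 ± 108 CPM and did not pass (-0.92 ± 0.25 log2, adjusted p = 0.0788), nor did Nppa, Acta1, Col1a1, Ankrd1, Myh7, Postn, Atp2a2 or Myh6 (adjusted p = 0.188 to 0.835). Cyp1a1, a target of the aryl hydrocarbon receptor, had 0 to 2 counts in any library and was not tested.

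The count of 126 depended on single libraries. Without air library 1 it was 1 (Cd93) and without air library 5 it was 19, while without air libraries 2 and 4 it was 352 and 377. Without nicotine libraries 2, 3, 5 and 6 it was 1 (Cd93), 4 (Cd93, Col4a1, Col4a2 and Pde10a), 10 and 36. Left without air libraries 1 and 5, a choice made after seeing the data, 7 genes passed, all lower, and 4 of them were collagens: Col4a1 (-0.96 log2, adjusted p = 0.0495), Col4a2 (-0.90, 0.0495), Col15a1 (-0.93, 0.0248) and Col6a1 (-0.64, 0.0248). The other 3 were Nrp2, Apln and Bub1b. In that fit the matrix list had camera adjusted p = 1.74e-20, the cell cycle list 2.93e-25, while cardiac stress genes (0.63), glycolysis genes (0.434), neutrophil markers (0.956) and adipocyte markers (0.0611) lost their calls. The log2 fold changes of the 126 genes then had a slope of 0.359 on those with all libraries, and 99.2% kept their sign. Fitted on the 8 libraries of both groups alone, the call was 1 gene (Slc41a3), and DESeq2 on all libraries called 471. The authors' deposited table for this comparison listed 138 genes under an adjusted p of 0.05, 40 higher and 98 lower, of which 81 were also among the 126.

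**Figure D2:**
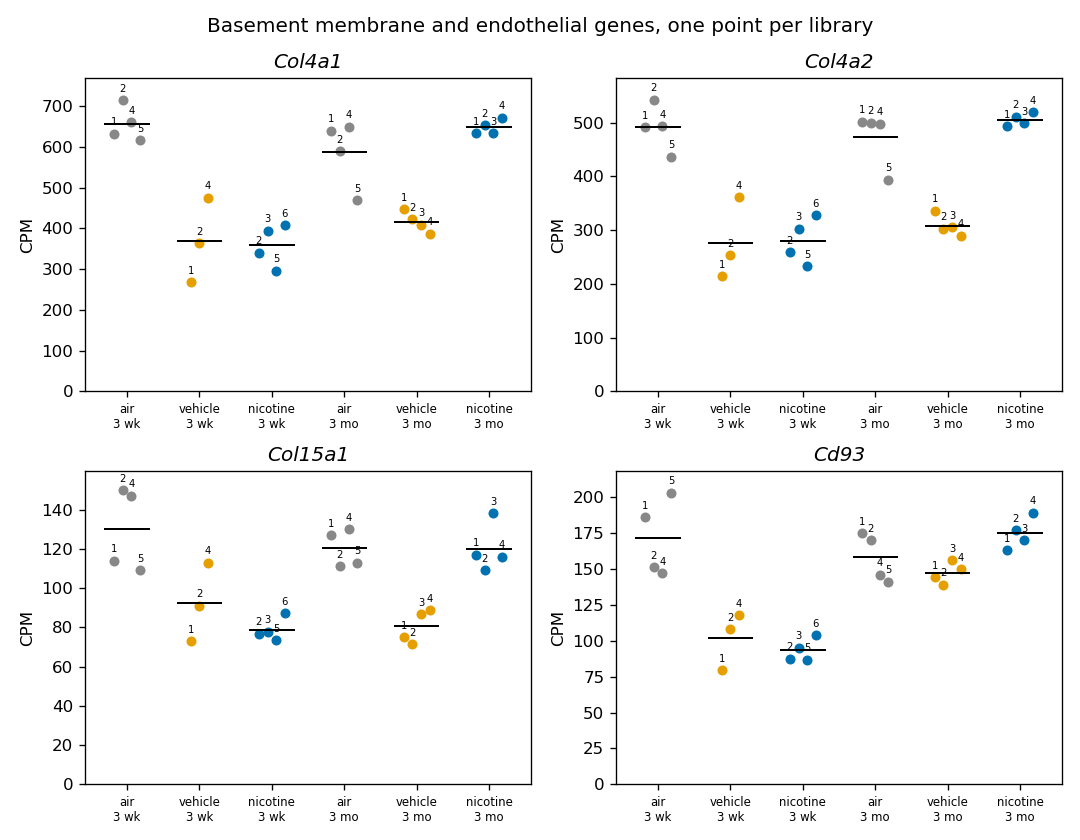
CPM of Col4a1, Col4a2, Col15a1 and Cd93 in each of the 23 libraries, with replicate numbers and group means as bars, on axes from 0. The 3-week vehicle and nicotine libraries lie under 3-week air for Col4a1 and Col4a2, and among the older mice the 4 vehicle libraries do.

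**Figure D3:**
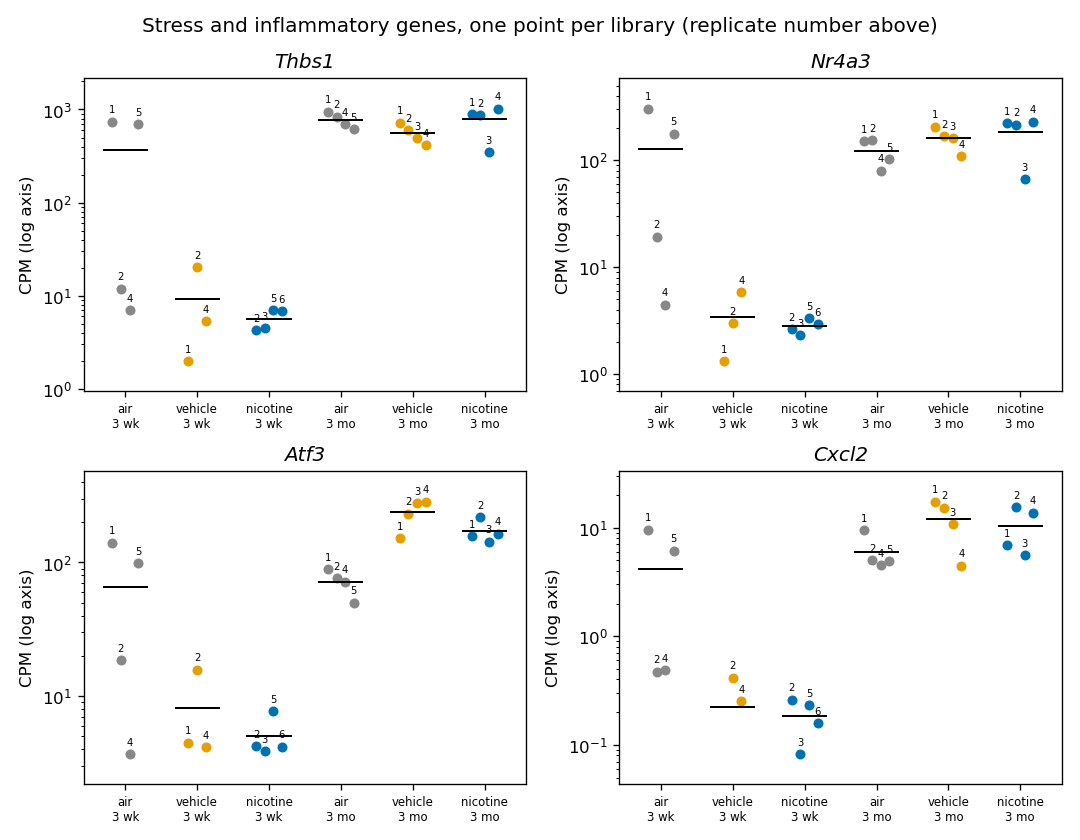
CPM on a log axis of Thbs1, Nr4a3, Atf3 and Cxcl2 in each of the 23 libraries, with replicate numbers and group means as bars. In 3-week air, libraries 1 and 5 lie near the levels of the older mice and libraries 2 and 4 lie lower. For Nr4a3, air library 2 still lies above the 3-week nicotine libraries. A Cxcl2 value of 0 CPM in 3-week vehicle library 1 is not drawn.

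Mice given vehicle aerosol from 3 weeks of age had lower levels of genes of fatty acid oxidation and of Col4a1 and Col4a2 than air controls. Pdk4, a kinase that restrains glucose oxidation, was at 88.3 ± 36.5 CPM (n = 3) against 456 ± 248 CPM (n = 4), a change of -2.37 ± 0.44 log2 (adjusted p = 0.0141), with every vehicle library (46.5 to 113 CPM) under every air library (132 to 711 CPM). Col4a2 and Col4a1 again were lower (-0.83 ± 0.15 log2 each, adjusted p = 0.0141). Upf2, of nonsense-mediated decay, rose to 50.1 ± 5.13 from 33.0 ± 1.08 CPM, and the splicing factor Prpf39 to 46.5 ± 13.6 from 24.9 ± 3.83 CPM (both adjusted p = 0.0141). In total 2509 genes passed, 1437 higher and 1072 lower. Scaled by RLE the split was 1266 higher and 1295 lower, and with the length offset 1204 and 1348.

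Of 25 measured genes of fatty acid oxidation, 12 fell and 16 fell adjusted over the list alone, including Cpt2 (-0.44 log2, adjusted p = 0.0215), Acadvl (-0.51, 0.0239) and Slc25a20 (-0.58, 0.0239). Camera gave the list adjusted p = 5.45e-07 and fry 0.0315, with adjusted p = 0.867 with an estimated correlation. Matrix genes had 8 of 27 lower and 12 adjusted over the list alone (camera adjusted p = 0.000234), glucose uptake and glycolysis genes 8 of 21 lower, with 8 lower and 1 higher over the list alone (0.00493), and glucocorticoid targets 7 of 18 lower and 1 higher, with 11 lower and 1 higher over the list alone (0.00493). NF-kB targets had 8 of 21 lower, with 13 lower and 1 higher over the list alone (0.0128). Ion channels were lower as a group, with 15 of 18 negative (0.033). Of 24 interferon genes 3 rose, 4 adjusted over the list alone, among them Ifit3 (0.93 log2, adjusted p = 0.0307), Stat2 and Oas2 (0.000234). These 6 lists had adjusted p = 0.867 with an estimated correlation. The sarcomere gene Myh7, the slow myosin heavy chain, rose to 4007 ± 753 from 2766 ± 358 CPM (0.54 ± 0.18 log2, adjusted p = 0.0477, and 0.0529 with the length offset), and Myh6, the fast chain, fell to 31350 ± 7503 from 42260 ± 6612 CPM (-0.43 ± 0.14, 0.0386). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 7243 ± 4578 against 14140 ± 5070 CPM and did not pass (adjusted p = 0.0532), nor did Col1a1, Acta1, Ankrd1, Postn, Nppb or Nppa (0.0825 to 0.934).

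These calls also rested on few libraries. None passed without air library 1 or without vehicle library 1, 107 passed without vehicle library 2 and 170 without air library 5, against 3328 without air library 2 and 6969 without vehicle library 4. With only these 7 libraries in the fit, 0 genes passed in edgeR (2363 at an unadjusted p under 0.05), as when air libraries 1 and 5 (2408) or vehicle libraries 1 and 2 (696, with the lone vehicle library assumed to vary like the other groups) were left out of the fit of all libraries, while DESeq2 called 3386. Without air libraries 1 and 5 the camera calls of NF-kB and glucocorticoid targets (adjusted p = 0.759 each), glycolysis (0.167) and ion channels (0.127) were lost, and without vehicle libraries 1 and 2 those of fatty acid oxidation (0.0701) and ion channels (0.845). Noncoding genes, whose share of counts was higher in vehicle libraries 1 and 2 than in the other vehicle and air libraries of this age, made up 23.7% of the higher calls, 4.57% of the lower calls and 12.8% of the genes tested.

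Between nicotine and vehicle aerosol from 3 weeks of age, every one of the 25 measured genes of fatty acid oxidation was higher with nicotine, and 19 passed adjusted over the list alone, though none passed over all genes. Pdk4 was at 343 ± 124 against 88.3 ± 36.5 CPM (1.95 ± 0.44 log2, adjusted p = 0.122), Ucp3 at 61.2 ± 18.6 against 19.7 ± 3.72 CPM and Hadha at 1661 ± 203 against 1066 ± 417 CPM. The list had a median of 0.57 log2, a camera adjusted p = 1.18e-17 and a fry adjusted p = 0.00419, with adjusted p = 0.195 with an estimated correlation. No gene passed the threshold in edgeR (2992 at an unadjusted p under 0.05), and DESeq2 called 255. The smallest p-values were those of Retsat (0.75 ± 0.12 log2, adjusted p = 0.0593), Slc25a34 (0.87) and Slc27a1 (0.54) among higher genes and Rnf213 (-0.56), Scgb1c1 (-0.92) and Bcl6b (-0.91) among lower ones. Also higher by camera were blood markers (0 of 6 called, 3 adjusted over the list alone, adjusted p = 0.000289), NRF2 genes (0 of 23, 3 over the list alone, 0.00982), xenobiotic metabolism (0 of 17 by either count, 0.00982), ion channels (0 of 18, 0.0158) and glycolysis (0 of 21, 0.027). Lower were interferon genes (0 of 24, 4 over the list alone, 0.000289), cell cycle genes (0 of 23, 0.000289) and immediate early genes (0 of 19, 0.0158). For these 8 lists the adjusted p = 0.549 to 0.977 with an estimated correlation. Without vehicle library 4, 4793 genes passed, 2606 higher and 2187 lower, and without any other vehicle or nicotine library of this age 0. Without vehicle libraries 1 and 2 the camera calls of interferon (adjusted p = 0.294), xenobiotic (0.161), glycolysis (0.168), immediate early (0.817) and ion channel genes (0.847) were lost, with the lone vehicle library assumed to vary like the other groups. The fatty acid oxidation list had a mean log2 CPM of 7.24 in that library, against 6.62 and 6.79 in vehicle libraries 1 and 2 and 7.4 to 7.77 in nicotine. The 9 fixed stress genes measured had adjusted p = 0.153 (Nppb) to 0.947.

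Nicotine aerosol from 3 months of age left no gene past the threshold against air with all 23 libraries in the fit. Etv5, a transcription factor, was at 19.6 ± 3.97 against 10.7 ± 0.74 CPM (n = 4 each, 0.88 ± 0.16 log2, adjusted p = 0.233), Phlda1 and Abra were 0.96 and 0.99 log2 higher, and Fign, Vwc2 and the potassium channel Kcnh2 were -0.89, -0.84 and -0.49 log2 lower (adjusted p = 0.821 to 1). Nppb was at 478 to 705 CPM against 222 to 415 CPM (0.79 ± 0.25 log2, adjusted p = 1), and the other stress genes also had adjusted p = 1. At an unadjusted p under 0.05 there were 408 of 15500 genes, a smaller share than the 0.05 that no effect would give on average. The test was thus strict here. Its common coefficient of variation was 0.179, against 0.105 in the older libraries alone, so the lack of calls does not show a lack of effect. DESeq2 called 1 (Etv5), and edgeR on these 8 libraries alone called 3, Phlda1, Myom2 and Slc38a2. Etv5 also passed without nicotine library 1 (adjusted p = 0.0224). Camera placed 6 lists higher: cardiac stress markers (12 of 13 positive, adjusted p = 3.72e-05), integrated stress (21 of 25, 0.000316), NF-kB targets (19 of 21, 0.00105), heat shock (13 of 14, 0.00105), interferon (23 of 24, 0.00852) and immediate early genes (19 of 19, 0.0125). Ion channels (0 of 18 called, 1 adjusted over the list alone) and atrial markers (0 of 7) were lower (0.0125 and 0.0208). In the 6 higher lists and the atrial markers no member passed by either count, and with an estimated correlation the 8 lists had adjusted p = 0.446 to 0.789. The authors' deposited table for this comparison listed 43 genes under an adjusted p of 0.05, led by Atf3 (log2 fold change 1.25, adjusted p = 1.33e-10). Of these, 0 passed here with all 23 libraries in the fit, whereas that table holds only the 8 libraries of this contrast. Phlda1, Myom2 and Slc38a2, called by edgeR on these 8 alone, were among the 43, as was Etv5. All 43 had the same sign here, which the use of the same libraries fixes in advance.

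Vehicle aerosol from 3 months of age gave lower levels of ion channel and calcium handling genes and of Col4a1 and Col4a2, and higher levels of Myh7 and Nppb than air, differences that passed or failed the test with the choice of libraries in the fit. Atp2a2 was at 9796 ± 1196 against 16580 ± 2186 CPM (n = 4 each), and the calcium release channel Ryr2 at 809 ± 95.2 against 1718 ± 363 CPM. Col4a2 was at 308 ± 19.2 against 473 ± 52.7 CPM, Myh7 at 5099 ± 623 against 3353 ± 682 CPM, and Nppb at 526 ± 45.7 against 324 ± 83.6 CPM. Fitted with all 23 libraries, 0 genes passed in edgeR, with 2200 at an unadjusted p under 0.05, and DESeq2 called 82. The adjusted p was 0.321 for Atp2a2, 0.221 for Myh7 and 0.299 for Nppb, and for Abcb9, Ncs1 and Slc41a3 (lower) and Phlda1, Scgb1c1 and Txndc12 (higher), the genes with the smallest p, it was 0.102. Without air library 5, 1 gene passed, Slc41a3 (-1.32 log2, adjusted p = 0.029). Fitted on the 8 libraries of both groups alone, 2635 genes passed, 1097 higher and 1538 lower. The fit of all libraries pools the more variable younger libraries with the older ones. Its common coefficient of variation was 0.179, against 0.105 in the older libraries alone, which makes tests among the older mice stricter.

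In that fit of the compared groups, 12 of 18 ion channel genes fell, among them Cacna1g (-0.66 log2, adjusted p = 0.00112), Kcnh2 (-0.49, 0.00262) and Hcn2 (-0.42, 0.00624). Of 15 measured calcium handling genes 7 fell and 1 rose, with Atp2a2 at -0.76 ± 0.10 log2 (adjusted p = 0.0021), Ryr2 at -1.08 (0.00237) and the sodium-calcium exchanger Slc8a1 at -1.72 (0.00633). Of 27 matrix genes 9 fell and 3 rose, with Fbn1 at -0.74 (0.00112), Col4a2 at -0.61 (0.00125) and Col4a1 at -0.49 (0.00432). Sat1, an enzyme of polyamine breakdown, rose most clearly (114 ± 8.46 against 64.9 ± 3.72 CPM, adjusted p = 0.00038), as did Myh7 (0.61 ± 0.14 log2, 0.0145) and Nppb (0.71 ± 0.17, 0.0174). Myh6 fell (-0.20 ± 0.06, 0.0405, and 0.169 with the length offset), and the other stress genes had adjusted p = 0.0986 to 0.919. Nuclear genes of oxidative phosphorylation had 13 of 30 higher and 2 lower, immediate early genes 8 of 19 higher (4 with the length offset), and endothelial markers 5 of 13 higher (6). Longer genes were lower: across genes the rank correlation of the log2 fold change (all libraries) with exonic length was -0.327, and called lower genes had a median length of 6634 against 2728 bases for higher ones and 4276 for those tested. With the length offset in this fit 1851 genes passed, 1581 of them also called without it and all 1581 of the same sign. Atp2a2 (adjusted p = 0.00285), Ryr2, Col4a2 and Myh7 (0.0195) kept their calls there, Nppb (0.0701) and Ndufa2 (0.0834) did not, and oxidative phosphorylation had 4 higher and 2 lower.

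By camera over all libraries, 13 lists passed for 3-month vehicle against air, and with an estimated correlation they had adjusted p = 0.577 to 0.859. Lower were ion channels (median -0.40 log2, 4 of 18 adjusted over the list alone, adjusted p = 4.03e-05), matrix genes (8 of 27 over the list alone, 0.000166), calcium handling (1 of 16, 0.0116), cholesterol synthesis (0 of 19, 0.035), fatty acid oxidation (0 of 25, 0.0439) and atrial markers (median -3.03, 2 of 7, 0.0439). Higher were oxidative phosphorylation (0 of 30, 0.00109), immediate early genes (19 of 19 positive, 0 over the list alone, 0.00109), interferon (2 of 24, 0.00406), endothelial markers (1 of 13, 0.00667), xenobiotic metabolism (5 higher and 2 lower of 17, 0.035), cell cycle (0 of 23, 0.0439) and blood markers (0 of 6, 0.0478). Over all genes 0 members were called. The trend with exonic length was not taken out of these list results.

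With nicotine aerosol from 3 months of age, basement membrane collagen and Atp2a2 stood higher and Myh7 lower than with vehicle aerosol. Col4a2 was at 506 ± 12 CPM with nicotine against 308 ± 19.2 CPM with vehicle, Atp2a2 at 16660 ± 1822 against 9796 ± 1196 CPM, and Myh7 at 3592 ± 382 against 5099 ± 623 CPM (n = 4 each). The 3-month air group stood near the nicotine group, at 473 ± 52.7, 16580 ± 2186 and 3353 ± 682 CPM. For these genes it was thus the vehicle group that stood apart, although the nicotine aerosol also held the vehicle. All 4 vehicle libraries had negative length trends. With all libraries in the fit, 0 genes passed in edgeR (1889 at an unadjusted p under 0.05; DESeq2 called 13), and Col4a2 (0.71 ± 0.13 log2) and Podn (-0.92 ± 0.17) had the smallest adjusted p, 0.171. Noc3l, Col4a1, Gsta3 and Ctla4 followed at 0.322 to 0.376. With the 8 libraries of these groups alone, 2247 genes passed, 1396 higher and 851 lower, including Col4a2 (0.69 ± 0.06 log2, adjusted p = 0.000106), Atp2a2 (0.74 ± 0.10, 0.000755), Ryr2 (0.88, 0.00271) and Myh7 (-0.53 ± 0.09, 0.00371). Nppb did not pass (0.07 ± 0.11 log2, 0.741), Myh6 (0.23, 0.0202) and Col1a1 (0.37, 0.0463) were higher, and with the length offset these last had 0.082 and 0.091. The other stress genes had adjusted p = 0.795 to 0.962. Of the genes called in both this and the vehicle contrast so fitted, 1608 in all, 1607 had opposite signs. The vehicle libraries are shared, which by itself pushes these contrasts to opposite signs, and no count for unrelated effects was computed to set beside it. Here too length was involved, since the rank correlation with exonic length was 0.356, and 1590 genes passed with the length offset, 1337 of them also without it.

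Camera placed 7 lists past its threshold for 3-month nicotine against vehicle: matrix genes (9 of 27 higher adjusted over the list alone, adjusted p = 5.43e-05), calcium handling (0 of 16, 0.011), ion channels (0 of 18, 0.011), hypoxia targets (1 of 16, 0.0346) and integrated stress (0 of 25, 0.0386) higher, with oxidative phosphorylation (0 of 30, 0.00199) and blood markers (0 of 6, 0.0346) lower. With an estimated correlation they had adjusted p = 0.7 to 0.882. Camera was not run with the length offset. Fitted on the compared groups, oxidative phosphorylation had 13 genes called lower and 2 higher, but 3 lower and 3 higher with the offset. Blood markers went from 4 to 1 lower and matrix genes from 10 to 7 higher. The oxidative phosphorylation and blood results may thus reflect the trend with length.

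**Figure D4:**
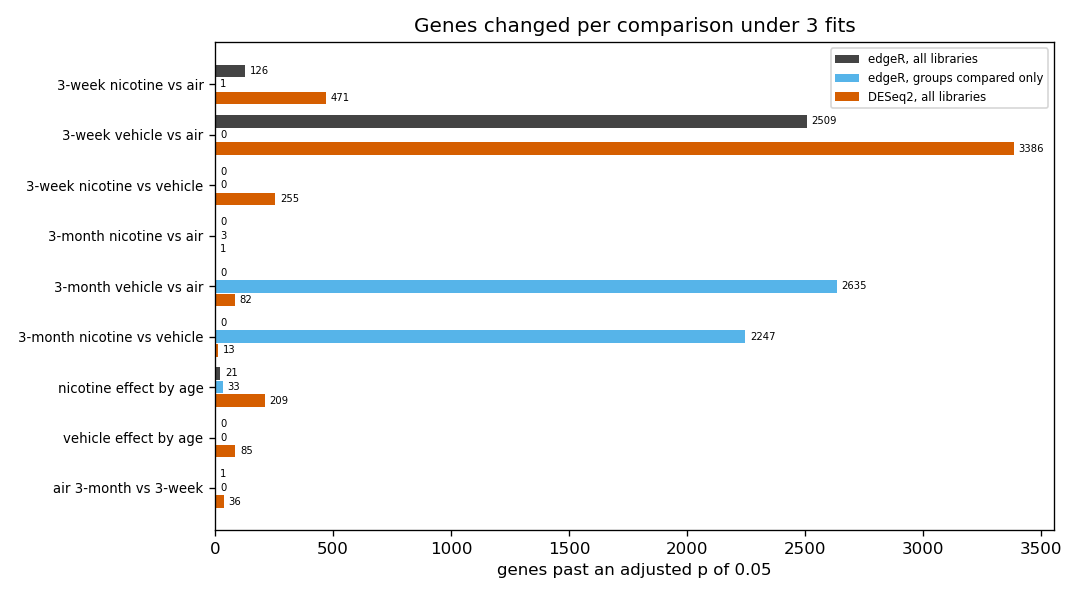
Number of genes past an adjusted p of 0.05 in each comparison under 3 fits: edgeR with all libraries, edgeR with the groups compared only, and DESeq2 with all libraries. The 3-week vehicle contrast had 2509 genes with all libraries and 0 with its own groups, and the 3-month vehicle contrast had 0 and 2635.

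The effect of nicotine aerosol differed between starting ages for 21 genes, 5 with a higher and 16 with a lower effect at 3 weeks. Abra, an actin-binding activator of muscle transcription, was at 56.1 ± 6.69 CPM with nicotine and 115 ± 50.2 CPM in air at 3 weeks, but 217 ± 50.1 and 109 ± 19.3 CPM at 3 months (difference of effects -2.03 ± 0.33 log2, adjusted p = 0.0213). Cd93 (-1.02 ± 0.17, 0.0213) and Col4a1 (-1.01 ± 0.19, 0.0302) fell with nicotine at 3 weeks, and Col4a1 was at 648 ± 17.9 against 586 ± 82.5 CPM at 3 months. Rit1, Vwc2, Zc3h6 and Vmac had the more positive effect at 3 weeks, and Phlda1, Tnfrsf12a, Etv5, Ret, Nr4a3, Myo1e, Atf3, Srxn1 and Tnfaip3 the more negative. Nppb lay just outside the threshold (-1.70 ± 0.35 log2, adjusted p = 0.0501), and the other fixed stress genes had adjusted p = 0.539 to 0.956. DESeq2 called 209 and the fit of these 4 groups 33. Starting age and age at the end of exposure cannot be told apart in this contrast.

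Of 14 lists that camera separated between ages, 11 had the more negative nicotine effect at 3 weeks. They were NF-kB targets (1 of 21 called, 17 adjusted over the list alone, adjusted p = 1.04e-12), matrix genes (1 of 27 and 7, 6.68e-10), immediate early genes (1 of 19 and 14, 1.08e-09), cardiac stress markers (0 of 13 and 5, 8.86e-06), heat shock (0 of 14, 0.000215), integrated stress (1 of 25 and 3, 0.000663), neutrophil markers (0 of 6 and 4, 0.00456), cell cycle (0 of 23, 0.0183), adipocyte (0 of 8) and macrophage markers (0 of 13, both 0.0206), and hypoxia targets (0 of 16 and 1, 0.0263). Blood markers (0 of 6, 0.00151), fatty acid oxidation (0 of 25, 0.0228) and mitochondrially encoded genes (0 of 13, 0.0445) had the more positive effect. With an estimated correlation these lists had adjusted p = 0.246 to 0.619. Single libraries moved the count of 21: it was 7, 131, 199 and 5 without 3-week air 1, 2, 4 and 5, and 6, 0, 7 and 10 without 3-week nicotine 2, 3, 5 and 6. It was 9, 6, 1 and 0 without 3-month air 1, 2, 4 and 5, and 6, 0, 24 and 0 without 3-month nicotine 1, 2, 3 and 4. Without 3-week air libraries 1 and 5 together, 1 predicted gene passed, and neutrophil (adjusted p = 0.483), adipocyte (0.0977) and hypoxia lists (0.0577) lost their camera calls.

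For vehicle aerosol the difference between ages passed for 0 genes in edgeR (1861 at an unadjusted p under 0.05), against 85 in DESeq2. Cish, Abra and Otud1 (-1.71, -1.85 and -2.81 log2, adjusted p = 0.136 to 0.167) had the smallest p among genes with the more negative effect at 3 weeks, and Upf2, Ppp1r1b and Bcl11b (0.67, 2.44 and 1.28, 0.136 to 0.186) among the others. All 9 stress genes had adjusted p = 0.406 or more. Camera gave 10 lists a more negative effect at 3 weeks: immediate early genes (2 of 19 adjusted over the list alone, adjusted p = 2.77e-05), fatty acid oxidation (1 of 25, 2.77e-05), glucocorticoid targets (11 of 18, 4.26e-05), NF-kB targets (11 of 21, 7.73e-05), NRF2 genes (0 of 23, 0.000415), cardiac stress markers (2 of 13, 0.00649), glycolysis (0 of 21, 0.0124), heat shock (0 of 14, 0.0124), xenobiotic metabolism (0 of 17, 0.026) and endothelial markers (0 of 13, 0.0296). With an estimated correlation they had adjusted p = 0.622 to 0.681. Without 3-week vehicle library 4, 1472 genes passed, and without 3-week air library 2 or 4, 40 and 71. Without 3-week air libraries 1 and 5 the lists of glucocorticoid targets and glycolysis (adjusted p = 0.629 each), cardiac stress (0.295), NF-kB targets (0.252) and xenobiotic metabolism (0.0747) lost their camera calls, and without 3-week vehicle libraries 1 and 2 fatty acid oxidation (0.8), cardiac stress and xenobiotic metabolism (0.376 each) and glycolysis (0.206) did.

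Nicotine and vehicle effects against air correlated across genes at r = 0.711 for the younger mice, with a covariance of 0.192. Both effects also fell with exonic length (rank correlations -0.213 and -0.217), and this trend was not taken out. Shared air libraries alone gave a simulated r of 0.456 and a covariance of 0.0366, and with the air libraries split between the contrasts r was 0.138 to 0.611. The simulations drew genes independently and gave both ages the spread of all 23 libraries. The coefficient of variation was 0.179 there, but 0.234 in the younger and 0.105 in the older libraries alone. Simulated covariances may thus be too low for the younger mice and too high for the older. Both contrasts called 11 genes higher, where independent lists would share 1.3, and 71 lower, where they would share 7.75. The air libraries are shared, which raises this overlap by itself, and the overlap from shared controls alone was not simulated. Among the older mice r was 0.474, against 0.494 simulated, the covariance was 0.0444 against 0.037, and split controls gave -0.0127 to 0.186, with 0 shared calls. Between ages, which share no library, the vehicle effects correlated at 0.356 (simulated 0.00608) and the nicotine effects at -0.204 (simulated 0.00217). The vehicle effects both fell with exonic length, with rank correlations of -0.217 at 3 weeks and -0.327 at 3 months. For nicotine these were -0.213 and 0.0129. The length trend was not taken out of these correlations. Genes are not independent replicates, so these 4 correlations carry no p-value.

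Air controls of the older start, compared with those of the younger, had lower levels of cell cycle and interferon genes. They were also older at the end of exposure, and a batch between the cohorts cannot be told apart from age. Mki67 and Top2a, markers of dividing cells, were at 3.16 ± 1.01 and 2.25 ± 0.75 CPM against 8.71 ± 5.55 and 5.87 ± 3.52 CPM (n = 4 each), and the interferon-induced GTPase Iigp1 at 13.3 ± 3.13 against 28.0 ± 5.11 CPM (adjusted p = 0.0918). All 23 cell cycle genes were lower, 15 adjusted over the list alone (camera adjusted p = 4.33e-12), as were all 24 interferon genes, 9 over the list alone (1.26e-12), both with adjusted p = 0.362 with an estimated correlation. Over all genes, 1 passed: Apod, a lipid carrier, rose to 18.4 ± 1.04 from 8.53 ± 1.78 CPM (1.11 ± 0.18 log2, adjusted p = 0.0426), with 1408 genes at an unadjusted p under 0.05 and 36 called by DESeq2. Macrophage markers (5 of 13 over the list alone, 6.14e-06), blood markers (0 of 6, 0.0247) and oxidative phosphorylation (0 of 30, 0.0301) were lower. Higher were fatty acid oxidation (1 of 25, Ucp3, 1.7e-06), immediate early genes (0 of 19, 6.99e-06), glucocorticoid targets (0 of 18, 0.000506), NF-kB targets (0 of 21, 0.000555), neutrophil (0 of 6, 0.00213) and cardiac stress markers (0 of 13, 0.00281). These 9 had adjusted p = 0.362 to 0.754 with an estimated correlation. Without 3-week air libraries 1 and 5, 849 genes passed (275 higher, 574 lower), and oxidative phosphorylation (0.616) and blood markers (0.289) lost their camera calls. Without 3-week air 1 alone 68 passed, without 3-week air 5 there were 7, and without 3-week air 2 or 4, or any of the 3-month air libraries, 0. The 9 stress genes had adjusted p = 0.368 or more.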

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

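The exact permutation of the immediate early genes, their range within 3-week air, the noncoding share, the matrix genes without 2 air libraries and the bound on endothelial markers were chosen after the results were seen; the fits without pairs of libraries behind the slopes and the length-matched genes had bounds written before their values.

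Groups were reassigned among their libraries and each split was tested like the real one. For the differences of effects between ages, 40 splits were used, the real one and others drawn at random from those possible. For 3-week nicotine against air, 2 of 35 splits called at least as many genes as the real 126, with a highest other count of 2594 when air libraries 1 and 5 changed places with nicotine libraries 2 and 5, so chance cannot be excluded. For 3-week vehicle against air 4 of 35 reached the real 2509, with a highest other of 5326 when air library 2 and vehicle library 4 changed places. For 3-week nicotine against vehicle the real count was 0, reached by 35 of 35, and another split called 6658. Other splits that call more genes than the real one, many times as many for nicotine against air and 6658 against 0 for nicotine against vehicle, point to a structure among the younger libraries that is not the labelled groups. In the split with 6658 this structure followed the trend with exonic length. Vehicle library 4 and nicotine libraries 3 and 6 (0.0996 to 0.2) stood against vehicle libraries 1 and 2 and nicotine libraries 2 and 5 (-0.348 to -0.212). The split with 2594 set air libraries 1 and 5 and nicotine libraries 3 and 6 (-0.0197 to 0.26) against the rest (-0.348 to -0.0459). That with 5326 set air libraries 1, 4 and 5 and vehicle library 4 (-0.0459 to 0.26) against the rest (-0.279 to -0.0707). Both were thus also ordered by this trend, though with narrow gaps. The cause of the length trend was not tested. For the vehicle effect by age, 40 of 40 splits reached the real 0 and the highest other called 1639. That split kept the younger labels and exchanged 3 older air with 3 older vehicle libraries, which turns the difference of the vehicle effects nearly into their sum, so it is no sign of an unlabelled structure.

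Among the older mice, with all libraries in the fit, the real count was 0 and 35 of 35 splits reached it for nicotine against air, vehicle against air and nicotine against vehicle, with a highest other of 0. Fitted on the compared groups alone, 1 of 35 splits, the real one, reached 2635 for vehicle against air (highest other 2) and 2247 for nicotine against vehicle (highest other 96). That is the smallest share these splits allow, it is not adjusted for the other comparisons split, and both contrasts hold the same vehicle libraries. Only these 2 contrasts were split in this fit, so a chance split is made less likely but is not excluded. The 21 genes whose nicotine effect differed between ages were reached by 1 of 40 splits, the real one, with a highest other of 12. This is the smallest share that the drawn splits allow, and it is not adjusted for the other comparisons. A chance split is therefore not excluded for these genes. For 3-month against 3-week air the real count of 1 was reached by 2 of 35 splits (highest other 1), so chance cannot be excluded.

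Immediate early genes were lower in 3-week nicotine than in 3-week air. The list mean ranged over 3.03 log2 CPM within the 4 air libraries, more than the difference of -1.55 between the group means, so a state of some air libraries may account for the difference. An exact permutation of the list mean gave p = 0.0857, which leaves an effect of nicotine aerosol open.

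In 3-week vehicle against air, 23.7% of the genes called higher were noncoding, against 12.8% of the genes tested, so a higher share of noncoding RNA in vehicle libraries may account for part of the calls. Without vehicle libraries 1 and 2, which leaves a lone vehicle library assumed to vary like the other groups, the log2 fold changes of the called genes had a slope of 0.364 on the original ones and 80.4% kept their sign, so those libraries alone are neither excluded nor shown. Without air libraries 1 and 5 the slope was 0.687 and 99.2% kept their sign, so these alone do not account for the size of the changes. The calls were lost, with 0 genes past the threshold in that fit, which also holds fewer libraries. Both fits share their other libraries, which by itself favours a positive slope and kept signs. For the nicotine calls against air the same slope was 0.359, with 99.2% of the signs kept.

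Matrix genes were lower in 3-week nicotine than in 3-week air. Without air libraries 1 and 5 the 5 called genes had a median of -0.903 log2, against -0.806 with them. The 5 were picked because they were called. Thbs1 among them was high in air libraries 1 and 5 but not in the other 3-week air libraries, so the median does not speak for it. A set of 179 genes matched on exonic length and level had a median of -0.0801 log2. Length as matched here thus does not account for a drop of that size, though this median holds no spread between libraries. Endothelial markers had a median of -0.0559 log2 (interval -0.24 to 0.0912, 13 markers), which gave no sign of fewer endothelial cells. That interval is over markers, which ran from -1.76 (Cldn5) to 0.27 (Egfl7), and holds no spread between libraries. Fewer endothelial cells are therefore not excluded. An unlabelled batch or collection day stays open, and an effect of the aerosol is a hypothesis these libraries could carry but not settle.

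Col4a2 read 394 CPM in 3-month air library 5, against 498 to 502 CPM in the other 3, the 1 outlier among 125 groups tested. About 1 in 20 such groups would be picked by chance.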

How the results depend on the processing

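The groups are small, the labels give no batch, and single libraries carry several counts. For every value below that differs from its result above, the cause was not tested. The fits without pairs of libraries, of a single age and with the length offset were added after seeing the data.

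Without a count filter, 76 genes passed for 3-week nicotine against air, 1279 for 3-week vehicle against air, 3 for 3-week nicotine against vehicle (Slc25a34, Retsat and Bcl6b) and 1 (Podn) for 3-month nicotine against vehicle. At a minimum count of 50 there were 1 for 3-week nicotine against vehicle (Retsat), 37 for the nicotine effect by age and 0 for air by age, and the nicotine effects of the ages correlated at -0.3. RLE size factors gave 36 for the nicotine effect by age.

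With only the groups compared, the counts were 1 for 3-week nicotine against air (Slc41a3), 0 for 3-week vehicle against air, 3 for 3-month nicotine against air, 2635 for 3-month vehicle against air, 2247 for 3-month nicotine against vehicle, 33 for the nicotine effect by age and 0 for air by age. With libraries of one age only they were 0 and 0 for 3-week nicotine and vehicle against air, and 7, 2721 and 2405 for the 3 older contrasts in that order. The pooled coefficient of variation of 0.179 lies below that of the younger libraries alone (0.234) and above that of the older (0.105). The counts of these contrasts moved in the direction that this gives, though fewer libraries also enter such fits. With the length offset the nicotine effect by age had 53. With the offset and only the groups compared there were 0 and 0 for the younger contrasts with air, 7, 1851 and 1590 for the older ones, 41 for the nicotine effect by age and 0 for air by age.

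With the replicate number as a block, 0 genes passed in every contrast. The numbers do not pair the libraries: 4 of 6 same-number pairs of the younger and 2 of 10 of the older mice correlated over 0.1, and 1 of 11 and 1 of 12 libraries were closest to their own number. With 1 surrogate variable, 0 passed for 3-week vehicle against air, 62 for the nicotine effect by age and 3 (Apod, Amy1 and Ndrg4) for air by age, and Oas2 reversed to -0.00894 log2 in 3-week vehicle against air.

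DESeq2 called 471 for 3-week nicotine against air, 255 for 3-week nicotine against vehicle, 1 (Etv5), 82 and 13 for the older contrasts, 209 and 85 for the nicotine and vehicle effects by age and 36 for air by age.

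Without 3-week air libraries 1 and 5, 7 genes passed for nicotine and 0 for vehicle against air, 1 for the nicotine effect by age and 849 for air by age. With only the groups compared as well these were 0, 0, 8 and 3435. Per1 in 3-week vehicle against air reversed to 0.0050 and 0.013 log2 in these fits. Without 3-week vehicle libraries 1 and 2, 0 passed for vehicle against air in either fit, with the lone vehicle library assumed to vary like the other groups. There the log2 fold changes reversed, in the fit of all groups and of the compared groups, for Itpr2 (-0.0753 and -0.0779), Ndufa2 (-0.15 and -0.15), Ndufa1 (-0.014 and -0.017), Sod1 (-0.091 and -0.094), Bax (-0.24 and -0.24) and Egfl7 (-0.070 and -0.074).

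With each library of the groups compared left out in turn, counts ran from 1 to 377 for 3-week nicotine against air, 0 to 6969 for 3-week vehicle against air, 0 to 4793 for 3-week nicotine against vehicle, 0 to 1 for both older contrasts with air, 0 to 0 for 3-month nicotine against vehicle, 0 to 199 and 0 to 1472 for the nicotine and vehicle effects by age, and 0 to 68 for air by age. Gene lists past the camera threshold, 95 over all contrasts, ran from 84 to 104. They were 0 with an estimated correlation and 5 by fry. Split air controls moved the correlation of nicotine and vehicle effects to 0.138 and 0.611 in the younger and to -0.0127 and 0.186 in the older mice.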

Other observations

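The exact permutations of list means given here were chosen after the results were seen.

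Immediate early genes varied less between libraries in the older groups than in the younger ones. They had a list mean of 6.54 ± 0.21 log2 CPM in 3-month air, 6.86 ± 0.11 in 3-month nicotine and 7.13 ± 0.21 in 3-month vehicle, against 5.64 ± 1.4, 4.08 ± 0.62 and 4.76 ± 1.1 in the younger air, nicotine and vehicle groups. Inflammatory and NF-kB genes had 2.66 ± 1.1 in 3-week air and 1.28 ± 0.14 in 3-week nicotine (exact permutation p = 0.0286, adjusted 0.12 over 21 tests), with 1.59 ± 0.37 in 3-week vehicle and 3.35 ± 0.16, 3.64 ± 0.39 and 3.68 ± 0.39 in the older air, vehicle and nicotine groups. Matrix genes had 5.36 ± 0.17 in 3-week nicotine against 5.9 ± 0.14 in 3-week air, and 5.75 ± 0.046 in 3-month vehicle against 5.98 ± 0.11 in 3-month air (exact p = 0.0286 and adjusted 0.12 for each), the smallest p that 4 against 4 libraries allow.

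Ucp3, a mitochondrial carrier, was at 27.2 ± 6.55 CPM in 3-week air, 19.7 ± 3.72 in 3-week vehicle, 61.2 ± 18.6 in 3-week nicotine and 83.6 ± 35.9 in 3-month air. Mki67 was at 13.2 ± 6.33 CPM in 3-week vehicle and 4.85 ± 2.01 CPM in 3-week nicotine. Abra stood at 217 ± 21.2 CPM in 3-month vehicle, beside 217 ± 50.1 CPM in 3-month nicotine and 109 ± 19.3 CPM in 3-month air.

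Libraries with negative length trends were not confined to a single group. They included 3-week nicotine libraries 2 and 5 (-0.348 and -0.298), 3-week vehicle libraries 1 and 2 (-0.212 and -0.279) and every 3-month vehicle library. Blood markers had a mean log2 CPM of 5.95 in 3-week nicotine library 6 and 3.35 in 3-month air library 4, the extremes.

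New animals with the batch and collection time recorded would help to separate the aerosol from a state of the younger libraries. A quantitative PCR of Col4a1, Col4a2 and Cd93, which in 3-week nicotine lay under 3-week air, is a direct next step. In the vehicle difference among the older mice, 2635 genes in its own fit, longer genes were lower, and the cause of this was not tested. Samples with RNA integrity recorded and matched would show whether it plays a part.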
